A study of Mus musculus with 6 samples.

How the data were processed

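The study holds 6 liver RNA samples from nude mice, 3 from mice injected with buffer and 3 from mice injected with vesicles of SW620 cells, and the treatment label of each sample put it in its group. RNA was labelled with Cy3 and hybridised to 1 array per liver, per the labels' protocols. Signals were read with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. The deposited scanner files hold processed signal as intensity, which per the file headers had the background subtracted and spatial trends removed within each array, low values replaced by a surrogate, and no scaling between arrays. They also hold the mean and local background intensity of each spot. The deposited value table is on a log2 scale. Its values were compared with the scanner files: across probes, which are not independent replicates, each column correlated with log2 of its array's processed signal (lowest r 0.9995), and all columns had a median of 4.50 and nearly equal sorted values, as quantile normalization gives. Its 56745 rows include 140 control probes. How it was made is not given in the sources used here beyond the software named.

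The main values were log2 of the processed signal minus the array's 75th percentile. Control spots and spots with outlier flags (91 to 171 per array) were left out, and spots of 1 probe were averaged. No spot outside the controls was saturated (0 on each array). Of 56605 probes with 37074 gene names, probes well above background on at least 3 of the 6 arrays were kept, and the probe with the highest mean stood for its gene name, which left 19446 genes, 5946 of them with placeholder names. Gene names are those of the array design. The accessions of 32989 probes matched the reference table of RefSeq genes, covering 22911 gene names, and for 1088 names the current symbol differs. Where a gene was not well above background on any array of 1 group, the fold is a bound: the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own. That floor is the lowest of any probe on the array. Folds given as "at least" therefore hold for this floor and scaling, and other processing can give a smaller change.

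Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The ± after a log2 fold change is its standard error from that fit, with 3 livers per group. An exact test of 3 against 3 cannot go below p = 0.1. Before the data were examined, 28 pathway and 16 cell type lists were fixed and tested with camera at a preset correlation of 0.01, adjusted over the 44 lists. Estimated correlations and fry were the alternatives. The counts over each list alone used the same p values adjusted within the list. The genes named in the text were set by a rule fixed then: the 12 largest rises and 12 largest falls among genes past the threshold with non-overlapping groups and no placeholder name, up to 4 members of each list by size of the moderated t among those past the threshold (otherwise the 2 highest and 2 lowest), and Alb, Actb and Gapdh. Genes chosen after their values were seen are named as such in the closing section.

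The fit was tested on simulated data for sEV versus control over 19446 genes, in 10 runs with the real genes' means, variances drawn from limma's fitted prior and 200 changed genes each. It called 16.2% of genes changed 1.5-fold, 64.2% at 2-fold, 93.8% at 4-fold and 98.0% at 8-fold, and 0.0359% of unchanged genes. Of 40 lists shifted by a log2 of 1, camera and fry each found 40, with 2 and 4 calls among 328 unshifted lists. These simulated genes were independent, so correlation between genes was not tested. Fewer genes were changed per run than the 3312 that passed in the data. The adjusted threshold depends on that share, so these rates describe the simulated setting only.

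All arrays were on 1 slide with 1 scan, so slide and scan could not be used as batches. Slide rows were taken as an alternative after the data were seen. Other alternatives changed background correction, scaling, the filter on dim probes, the probes per gene, the variance model, array weights, the value table, and left out each array in turn. Among control and sEV samples that share a number in the labels, deviations from the group means correlated at 0.02, 0.16 and 0.02, which is not over 0.1 for each pair, so that the numbers were not taken as pairs. The labels give 1 liver per array, and the 2 most alike arrays correlated at 0.995 across genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.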

Results

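Liver RNA was measured on 6 Agilent 1-colour arrays, 1 liver per array, from nude mice, an athymic strain that lacks mature T cells. The sEV group received small extracellular vesicles, membrane particles that cells release, purified from SW620, a human colorectal cancer cell line. Each tail vein injection held 20 µg of vesicles, and 10 injections were given over 21 days. Control mice received sterile buffer on the same schedule. Each group had 5 mice, and 3 livers per group were arrayed. The sEV mice that were arrayed were picked at random. The series title and design text put the question in terms of inflammation, macrophage polarization, apoptosis and matrix remodelling in the liver. The design text also reports from these same arrays that genes of inflammation, apoptosis and matrix remodelling changed, so the lists on those themes are not independent evidence of their direction. Each array carried 62976 spots, of which 59305 were not controls, and between 49.9% and 54.7% of those 59305 were well above background. The median share was 54.4% for control and 51.0% for sEV arrays. Before scaling, the 75th percentile of the processed signal was 440 to 506 on control arrays and 402 to 424 on sEV arrays. The number of arrays limits the precision of every value. Xist was well above background on all 6 arrays, and the Y-linked genes Ddx3y, Eif2s3y and Uty were so on 0 of them.

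Livers of vesicle-injected mice had lower expression of cell division genes and higher expression of acute phase genes than control livers. The rise with the largest fitted size was that of Saa3, an acute phase serum amyloid gene, from a normalized log2 signal of 1.84 ± 0.22 (SD, n = 3) to 8.38 ± 0.80 (SD, n = 3), a 92.5-fold difference (limma adjusted p = 0.000513). Next among the rises, leaving out genes with only a bound, were Sult1e1, an oestrogen sulfotransferase, at a log2 fold change of 4.67 ± 0.66 (SE), and Cxcl13, a B cell chemokine, at 3.85 ± 0.24. Among the falls, Ckap2, a spindle protein gene, was not well above background on any sEV array and was at least 38.2-fold lower. Among the alternatives the smallest log2 fold change of Ckap2 was -3.57, so such bounds hold for the main processing only. Cdc20, an activator of the anaphase-promoting complex, fell by 5.20 ± 0.18 on the log2 scale, a 36.7-fold difference (adjusted p = 0.000139).

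Of 19446 genes tested with limma, 3312 (17.0%) passed an adjusted p of 0.05, 1766 higher and 1546 lower in sEV livers. The higher calls made up 53.3% of the changed genes, against 36.9% when arrays were scaled to their median. At an unadjusted p under 0.05 with a change of at least 2-fold there were 995 genes, 433 higher and 562 lower. Of these, 75 have only a bound on their change that is under 2-fold. Among the genes that passed the adjusted threshold, 17 had a fitted change of at least 8-fold upward and 75 downward, or 12 and 50 when genes dim in 1 group are taken at their bound. The 3 sEV arrays did not overlap the 3 control arrays for 40.9% of genes, where chance gives 10%. Correlations across genes were 0.991 to 0.995 between livers of 1 group and 0.975 to 0.984 between groups, with genes not being independent replicates. Principal component 1 held 61.2% of the variance and separated the groups. All controls and sEV 1 lay in row 1 of the slide and the other sEV arrays in row 2. With slide row as a block, 715 genes passed, of which 606 were among the 3312 with the same direction, and within row 1 alone 594 passed. The blocked contrast rests on 1 sEV array, which is in both fits, and the fold changes of the fits correlated at 0.905 across genes.

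By fitted size, the other genes among the 12 largest rises were Slc10a6, Scara5, Treh, Orm3, Pde6h, Bmper, Cxcl1, Chil1 and Cep55. Slc10a6, a steroid sulfate transporter, was not well above background on any control array and was at least 4.64-fold higher. Pde6h, likewise not well above background in controls, was at least 6.56-fold higher. Treh, which encodes trehalase, rose by 3.45 ± 0.13 on the log2 scale, and Orm3, an orosomucoid gene, by 3.44 ± 0.42. Scara5, a ferritin receptor gene, rose by 3.65 ± 0.47, with 2 of 3 control arrays well above background, as for Cxcl13. The other, dimmer Scara5 probe gave 1.42 (adjusted p = 0.0173). Bmper, a modulator of bone morphogenetic protein signalling, rose by 3.31 ± 0.43, and Chil1, a chitinase-like protein gene, by 3.30 ± 0.23. Cxcl1, a neutrophil chemokine, had a log2 fold change of 3.31 ± 0.67 (adjusted p = 0.0241). Its adjusted p was 0.0849 without control 1, 0.0720 without control 2, 0.0594 without control 3, 0.0552 without sEV 2 and 0.0710 without sEV 3. Its log2 fold change was 4.11 without sEV 1 and 1.70 with slide row as a block (adjusted p = 0.0650). Cep55, a gene of the last step of cell division, rose by 3.20 ± 0.33, against the direction of the other division genes. Slide row as a block ended the calls of Sult1e1 (5.03, adjusted p = 0.0633), Orm3 (3.17, 0.0618) and Bmper (2.83, 0.0683), at log2 fold changes near those without it.

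**Figure D1:**
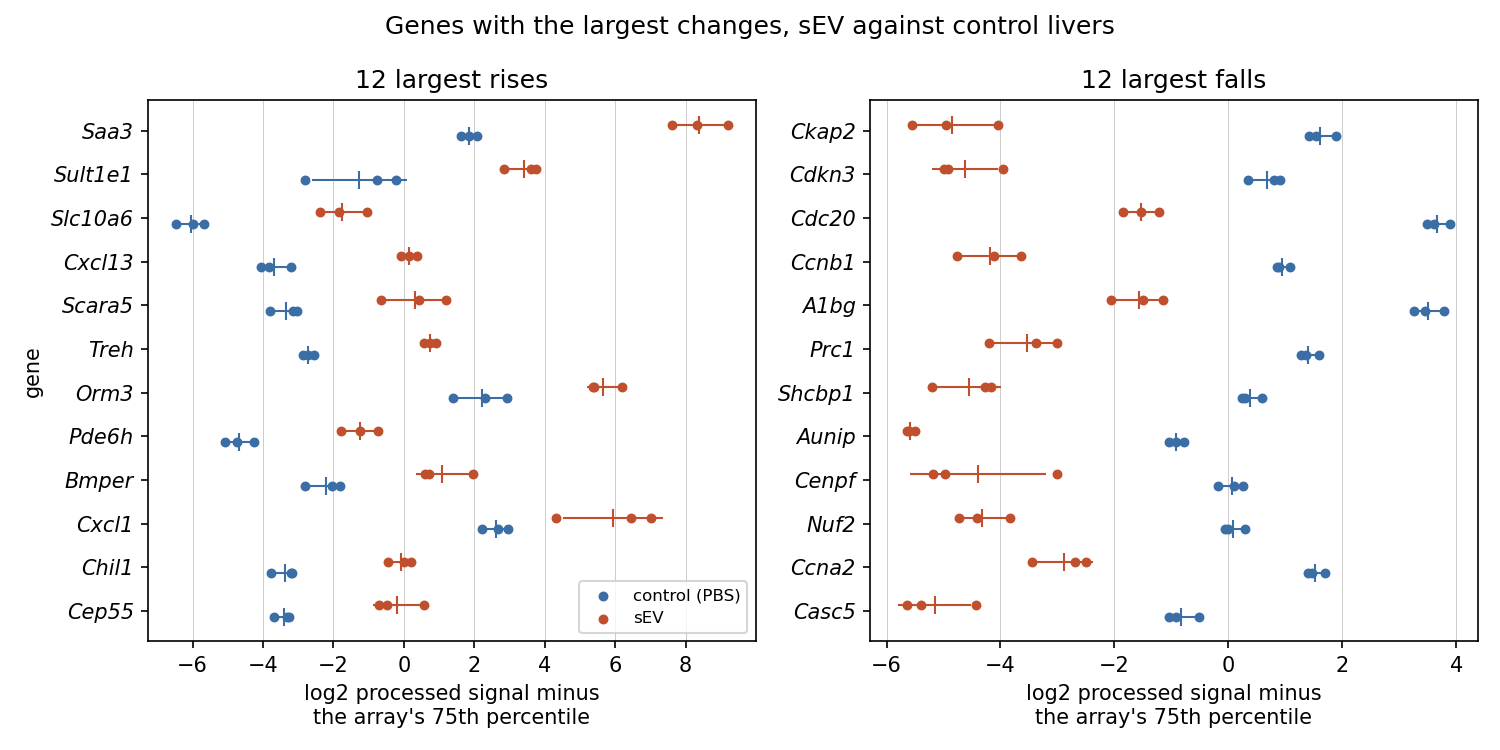
Normalized log2 signal (processed signal minus the array's 75th percentile) of the 12 genes with the largest fitted rise and the 12 with the largest fitted fall. Points are single livers, ticks are group means and bars are the SD of 3 livers per group, and for Saa3 the means are 1.84 in control and 8.38 in sEV livers.

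Genes of cell division fell together. Of 30 measured cell cycle genes, 27 fell, 0 rose and 3 did not pass, and the median log2 fold change was -2.63. Ccnb2, a mitotic cyclin gene, fell by 4.14 ± 0.16 on the log2 scale, and Birc5, which encodes the mitotic and anti-apoptotic protein survivin, fell by 3.61 ± 0.13. Aurkb, a mitotic kinase gene, was not well above background in sEV livers and was at least 5.76-fold lower. Among the 12 falls with the largest fitted size, Cdkn3 (at least 20.0-fold), Ccnb1 (at least 24.0-fold), Shcbp1 (at least 16.2-fold), Aunip (at least 6.61-fold), Nuf2 (at least 13.2-fold) and Casc5 (at least 7.06-fold) were lower and likewise not well above background on any sEV array. Prc1, a cytokinesis gene, fell by 4.94 ± 0.30 and Ccna2, a cyclin gene, by 4.40 ± 0.25, each with 2 of 3 sEV arrays well above background. Cenpf, a kinetochore gene, fell by 4.45 ± 0.56, with 1 of 3 sEV arrays well above background. The camera test gave an adjusted p of 1.09e-24 for the list, and an adjusted p of 0.489 with an estimated correlation. With 5 members set at their bounds the median was -2.31, and under normexp background correction it was -1.67. With slide row as a block, 22 of the 27 genes passed in the same direction and the blocked median was -2.68. Ccne2, a cyclin gene named after its values were seen, did not pass without the block (1.08, adjusted p = 0.304) and was higher with it (2.72, adjusted p = 0.0101).

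Erythroid markers were lower alongside the cell division genes. All 12 measured erythroid genes had negative log2 fold changes, of which 4 fell and 8 did not pass. Ahsp, a haemoglobin chaperone gene, fell by 3.59 ± 0.34 on the log2 scale, with 1 of 3 sEV arrays well above background, and Slc4a1, the red cell anion exchanger gene, fell by 1.79 ± 0.32. Car2, a carbonic anhydrase gene, fell by 0.68 ± 0.12, and Klf1, an erythroid transcription factor gene, by 0.50 ± 0.13, a call that ended under normexp. The camera adjusted p was 0.000613, and it was 0.489 with an estimated correlation. In the fit blocked by slide row 1 of the 4 genes passed, and the median was -0.45, against -0.68 without the block. Adjusted over the list alone, 4 genes fell, as 28 did for the cell cycle list.

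Acute phase genes, which the liver induces in inflammation, were higher in sEV livers. All 26 measured members had positive log2 fold changes, of which 18 rose and 8 did not pass, and the median was 1.18. Besides Saa3, Orm2 rose by 1.86 ± 0.20, Orm1 by 1.47 ± 0.16, and Lcn2, which encodes an iron-siderophore binding protein, by 2.66 ± 0.30. The list had a camera adjusted p of 9.60e-12, and an adjusted p of 0.489 with an estimated correlation. Of the 27 measured genes of inflammatory signalling, 13 rose, 0 fell and 14 did not pass. Irak3, a brake on Toll-like receptor signalling, rose by 2.59 ± 0.25, with 1 of 3 control arrays well above background. Cd14, a lipopolysaccharide co-receptor gene, rose by 1.93 ± 0.30, the interleukin 1 receptor gene Il1r1 by 1.87 ± 0.23, and Stat3, a mediator of interleukin 6 signals, by 0.83 ± 0.13. The camera adjusted p of the signalling list was 1.44e-07, and it was 0.489 with an estimated correlation. With slide row as a block, 4 of the 18 acute phase genes and 1 of the 13 signalling genes passed, and the blocked medians were 0.83 and 0.39. Adjusted over the list alone, 23 acute phase genes and 18 signalling genes rose. The study reports these same arrays on this theme, so the counts are not independent evidence of its direction.

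Among 20 measured cytokines and chemokines, 4 rose, 1 fell and 15 did not pass. Besides Cxcl13 and Cxcl1, the chemokine genes Ccl5 and Cxcl16 rose, by 0.79 ± 0.15 and 0.37 ± 0.08. The call of Cxcl16 ended under median scaling, among other alternatives. The median of the list was -0.01 and its mean 0.31, which differ in sign, and camera leaned upward with an adjusted p of 0.691. Of 21 measured factors of the pre-metastatic niche, tissue changes that precede metastasis, 8 rose, 2 fell and 11 did not pass (camera adjusted p = 0.353). Saa1, a serum amyloid gene, rose by 2.92 ± 0.49, and S100a4, a calcium-binding protein gene, by 1.08 ± 0.17, while Postn, which encodes the matrix protein periostin, fell by 1.48 ± 0.16. Interferon response genes moved both ways, with 5 of 29 higher, 6 lower and 18 not passing (camera adjusted p = 0.374). The interferon-stimulated genes Isg15, Rsad2 and Ifit1 fell by 1.14 ± 0.09, 1.40 ± 0.16 and 1.19 ± 0.14, while Gbp2, a guanylate-binding protein gene, rose by 0.84 ± 0.11. With slide row as a block the interferon list turned direction, with a median of 0.26 in place of -0.08, 5 genes higher and 1 lower. The count adjusted over the list alone was 5 up and 1 down for cytokines, 9 up and 6 down for niche factors, and 5 up and 6 down for interferon genes. The inflammation and niche themes are those of the study itself, so their counts are not independent evidence.

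Some markers of several innate immune cells were higher. Of 15 measured neutrophil markers, 8 rose, 0 fell and 7 did not pass, with a median log2 fold change of 1.18. Those that rose included the granule protease genes Ctsg, at 2.09 ± 0.25, and Elane, at 1.32 ± 0.16. Myeloperoxidase, Mpo, at 2.02 ± 0.40 and Lcn2, which is also on the acute phase list, rose as well. Among the 7 that did not pass were Ly6g (-0.07), Csf3r (-0.89), Cxcr2 (0.84), Retnlg (0.58) and Mmp8 (1.01). These genes were named after their values were seen. Of 15 Kupffer cell markers, 8 rose and 7 did not pass, among them the complement genes C1qa (0.74 ± 0.13) and C1qc (0.76 ± 0.13), Cd207 (0.91 ± 0.14) and Il18bp (0.64 ± 0.09). Of 13 dendritic cell markers, 5 rose and 8 did not pass, and the 5 were genes of antigen presentation on class II molecules, including H2-Eb1 at 1.52 ± 0.18, H2-Ab1 at 1.29 ± 0.17, Cd74 at 1.39 ± 0.16 and their regulator Ciita at 1.64 ± 0.32. Camera adjusted p values were 0.000233 for neutrophil, 0.00053 for Kupffer cell and 0.0163 for dendritic cell markers. In the same order, the adjusted p was 0.489, 0.495 and 0.489 with an estimated correlation. The counts adjusted over the list alone were 11, 11 and 5 genes higher. Blocking by slide row left 1 of the 8 neutrophil, 0 of the 8 Kupffer cell and 1 of the 5 dendritic cell calls, with blocked medians of 0.83, 0.58 and 0.83, against 1.18, 0.59 and 0.51 without the block.

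Monocyte and infiltrating macrophage markers moved both ways. Of 17 measured, 5 rose, 4 fell and 8 did not pass (camera adjusted p = 0.275). Cx3cr1, the fractalkine receptor gene, fell by 2.17 ± 0.16 and Ly6c2 by 0.56 ± 0.08, while Ms4a7, a macrophage membrane protein gene, rose by 1.27 ± 0.17. Ly6c1 had a log2 fold change of -0.52 ± 0.08 on the brighter probe and 1.58 on its other probe. Of 14 measured genes of M1-type activation, 2 rose and 1 fell (camera adjusted p = 0.578). Socs3, a feedback inhibitor of cytokine signalling, rose by 2.60 ± 0.53 and the formyl peptide receptor gene Fpr2 by 0.76 ± 0.13, and the chemokine gene Cxcl10 fell by 1.41 ± 0.35. Of 16 M2-type genes, 2 rose and 14 did not pass (camera adjusted p = 0.525). They were Chil3, a chitinase-like gene, at 2.51 ± 0.43 and Arg1, an arginase gene that hepatocytes also express strongly, at 0.59 ± 0.11. Of 13 T and NK cell markers 2 rose (camera adjusted p = 0.100), Nkg7 at 1.29 ± 0.21 and Ncr1 at 0.65 ± 0.14. Of 10 B and plasma cell markers 1 rose and 3 fell (camera adjusted p = 0.674). The B cell genes Ms4a1 (at least 2.04-fold) and Cd79b (-1.02 ± 0.20) were lower, and Jchain, an immunoglobulin joining chain gene, was higher at 0.72 ± 0.17. The B cell list had a median of 0.09 and a mean of -0.27, which differ in sign, and camera leaned downward. Counts up and down adjusted over the list alone were 7 and 4 for monocyte, 2 and 1 for M1-type, 2 and 0 for M2-type, 3 and 1 for T and NK and 2 and 4 for B cell genes. Macrophage polarization is named in the series title, so these counts are not independent evidence on it.

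Genes of the extracellular matrix were lower. Of 30 measured matrix protein genes, 13 fell, 1 rose and 16 did not pass, with a median of -0.69. Sparc, a collagen-binding glycoprotein gene, fell by 1.60 ± 0.13 and the collagen gene Col3a1 by 1.89 ± 0.28. Eln, the elastin gene, was not well above background in sEV livers and was at least 4.43-fold lower. Of 16 stellate cell and fibroblast markers, 5 fell and 11 did not pass, with Lrat, a retinol-storage enzyme gene, at -1.09 ± 0.17, Col1a1 at -2.04 ± 0.36 and Ngfr at -0.73 ± 0.17. Of 24 genes of TGF-beta signalling and stellate cell activation, 7 fell and 1 rose. Inhba, an activin subunit gene, fell by 1.52 ± 0.11, Cyr61 by 1.36 ± 0.21 and Tgfbi by 0.98 ± 0.15. Camera adjusted p values were 1.13e-05 for matrix proteins, 0.0188 for stellate markers and 0.0142 for the TGF-beta list. These adjusted p values were 0.489, 0.503 and 0.539 with an estimated correlation. The stellate call ended under quantile normalization (adjusted p = 0.0561), in the authors' table (0.0564), with array weights (0.0696), with slide row as a block (0.125), within row 1 (0.103) and without control 1 (0.0913), and the TGF-beta call ended without control 1 (0.0813). Blocking by slide row left 3 of the 14 matrix, 0 of the 5 stellate and 3 of the 8 TGF-beta calls, with blocked medians of -0.76, -0.13 and -0.26, against -0.69, -0.30 and -0.12 without the block. Counts adjusted over the list alone were 17 matrix, 5 stellate and 9 TGF-beta genes lower and 2, 0 and 2 higher. Matrix remodelling is a theme that the study reports from these arrays, so the counts are not independent evidence of its direction.

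Matrix remodelling enzymes and inhibitors moved both ways, with 3 of 28 higher, 6 lower and 19 not passing (camera adjusted p = 0.119). Mmp7, the matrilysin gene, rose by 2.98 ± 0.24 and Ctss, a cathepsin gene, by 0.65 ± 0.10. The metalloproteinase genes Adamts9 and Adamts1 fell by 2.35 ± 0.20 and 0.85 ± 0.09. Of 35 measured apoptosis genes, 4 rose, 7 fell and 24 did not pass (camera adjusted p = 0.159). Besides Birc5, which is on the cell cycle list as well, the death receptor gene Tnfrsf10b fell by 1.99 ± 0.21 and the survival gene Bcl2 by 0.80 ± 0.09. The other Bcl2 probe gave -0.49 (adjusted p = 0.0909). Bmf, a pro-apoptotic BH3-only gene, fell by 1.79 ± 0.21 on the brighter probe, and its other probe gave 0.10. These falls thus included genes that restrain and genes that promote cell death. Adjusted over the list alone, 5 remodelling genes rose and 8 fell, and 6 apoptosis genes rose and 9 fell. The study reports both themes from these arrays, so these counts too are not independent evidence.

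Periportal and other hepatocyte genes were higher. Of 13 periportal markers, 9 rose and 4 did not pass, with a median of 0.61. They included Sds, a serine dehydratase gene, at 1.52 ± 0.16, Pck1, the gluconeogenic enzyme gene, at 0.79 ± 0.09, and the urea cycle gene Ass1 at 0.80 ± 0.11. Asl, another urea cycle gene, had 1.15 ± 0.18 on the brighter probe and -0.06 on its other probe. Of 15 general hepatocyte markers 6 rose and 9 did not pass, among them Cps1 at 0.85 ± 0.09, Hnf4a at 0.54 ± 0.10 and Serpina1c at 0.33 ± 0.08. Of 13 pericentral markers 2 rose, Cyp27a1 (0.72 ± 0.08) and Rhbg (0.58 ± 0.15), and Lect2 fell by 0.62 ± 0.09 (camera adjusted p = 0.167). Of 20 genes of gluconeogenesis and fasting, 8 rose and 12 did not pass, with Tat, the tyrosine aminotransferase gene, at 1.20 ± 0.12 and Igfbp1, a fasting-induced binding protein gene, at 1.84 ± 0.19. Camera adjusted p values were 9.70e-05 for periportal, 0.000881 for hepatocyte and 0.000785 for gluconeogenesis genes. Each had an adjusted p of 0.489 with an estimated correlation. The hepatocyte call ended under quantile normalization (adjusted p = 0.301) and in the authors' table (0.236), as did that of Serpina1c, and median scaling ended the calls of Serpina1c and Rhbg. In the fit blocked by slide row 2 of the 9 periportal, 1 of the 6 hepatocyte and 5 of the 8 gluconeogenesis genes passed, with medians of 0.63, 0.27 and 0.69, against 0.61, 0.28 and 0.29 without the block. Counts adjusted over the list alone were 11 periportal, 6 hepatocyte, 4 pericentral and 9 gluconeogenesis genes higher, and 1 pericentral gene lower.

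Genes of lipid synthesis and oxidation were lower in part. Of 24 cholesterol synthesis and uptake genes, 10 fell, 0 rose and 14 did not pass, with a median of -0.81. Mvd, Msmo1 and Hmgcs1, which encode enzymes of the pathway, fell by 2.34 ± 0.42, 1.61 ± 0.29 and 1.60 ± 0.29, and Stard4, a cholesterol carrier gene, by 0.85 ± 0.11. Of 30 PPAR-alpha target and fatty acid oxidation genes, 8 fell, 1 rose and 21 did not pass. The acyl-CoA thioesterase genes Acot1, Acot2 and Acot3 fell by 1.64 ± 0.17, 0.61 ± 0.08 and 1.70 ± 0.23, and Vnn1, a pantetheinase gene, by 1.95 ± 0.23. Camera adjusted p values were 2.17e-06 and 0.00231, and they were 0.489 and 0.495 with an estimated correlation. With slide row as a block 9 of the 10 cholesterol genes and 3 of the 9 PPAR-alpha genes passed, with medians of -1.22 and -0.14, against -0.81 and -0.15 without the block. Fatty acid and triglyceride synthesis genes moved both ways, with Acacb (0.51 ± 0.10) and Dgat1 (0.32 ± 0.08) higher, Fads2 (-0.63 ± 0.13) and Elovl5 (-0.49 ± 0.12) lower and 18 of 22 not passing (camera adjusted p = 0.561). The calls of Acacb and Dgat1 ended under median scaling, among other alternatives. The other Elovl5 probe gave -0.23 (adjusted p = 0.377), and the other Fads2 probes gave from -1.17 (0.0329) to -0.45 (0.0932). Adjusted over the list alone, 1 cholesterol gene rose and 14 fell, 1 PPAR-alpha gene rose and 8 fell, and 4 fatty acid synthesis genes rose and 2 fell.

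Of 23 bile acid synthesis and transport genes, 7 rose, 1 fell and 15 did not pass. The transporter genes Slc51b and Abcb11 rose by 1.64 ± 0.13 and 0.67 ± 0.09, as did the synthesis gene Cyp27a1, and Slco1a1, an uptake transporter gene, fell by 3.14 ± 0.31. The list had a camera adjusted p of 0.00384, and an adjusted p of 0.489 with an estimated correlation. Of 31 xenobiotic metabolism genes 6 rose and 25 did not pass (camera adjusted p = 0.0682, with a median of 0.16 that turned to -0.03 under quantile normalization), with the cytochrome P450 genes Cyp2b10, Cyp2b9 and Cyp3a13 at 1.15 ± 0.12, 0.69 ± 0.12 and 0.96 ± 0.18 and Sult1d1, a sulfotransferase gene, at 1.37 ± 0.18. The sex-biased and growth hormone responsive list had 5 of 26 genes higher and 5 lower (camera adjusted p = 0.472). Its median was -0.29 with slide row as a block, against -0.02 without it. A1bg, which is expressed more in female liver, fell by 5.07 ± 0.25. Hsd3b5, Mup3 and Slco1a1, which are expressed more in male liver, fell as well, Hsd3b5 by 3.41 ± 0.44 and Mup3 by 1.52 ± 0.17 on its brightest probe, while the other Mup3 probes gave -0.39 (adjusted p = 0.270) and -0.25 (0.207). Of 30 complement and coagulation genes 8 rose and 2 fell, with C6 at 0.87 ± 0.11, C9 at 0.73 ± 0.12, F11 at -0.93 ± 0.12 and Mbl2 at -0.74 ± 0.10. The camera adjusted p was 0.0114, and it was 0.623 with an estimated correlation. Blocking by slide row left 3 of the 8 bile acid and 0 of the 10 complement calls, with medians of 0.28 and 0.17, against 0.32 and 0.17 without the block. The complement call also ended under normexp (adjusted p = 0.0609), under quantile normalization (0.203), in the authors' table (0.197), without the filter on dim probes (0.0953), with slide row as a block (0.0547) and without sEV 3 (0.0627). Counts adjusted over the list alone were 7 bile acid, 7 xenobiotic, 5 sex-biased and 11 complement genes higher and 1, 0, 6 and 2 lower.

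**Figure D2:**
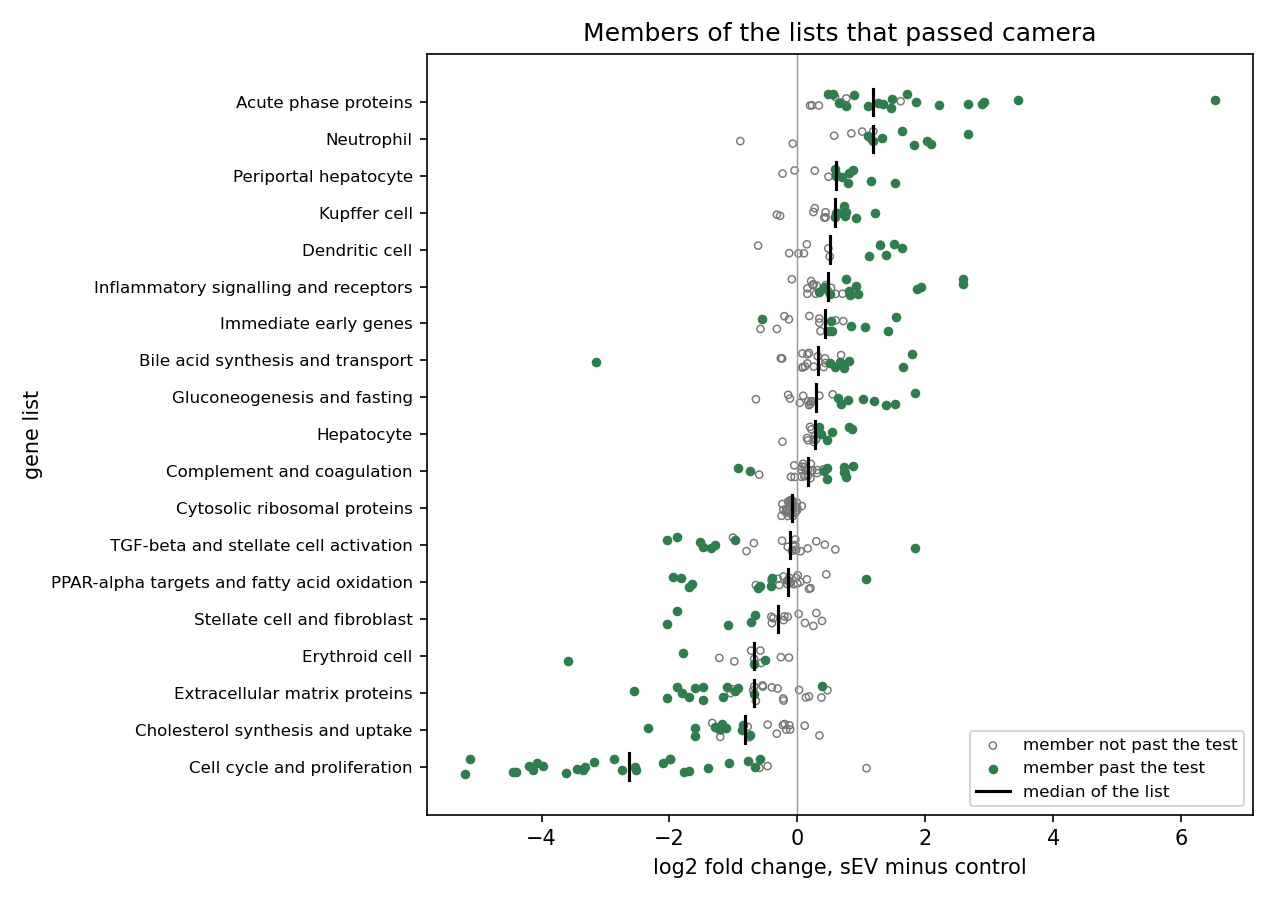
Log2 fold change (sEV minus control) of each measured member of the 19 lists that passed camera, ordered by list median. Filled points passed the limma test, open points did not, and black bars are medians, from -2.63 for cell cycle genes to 1.18 for acute phase proteins, while the small median of ribosomal protein genes is -0.09.

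Circadian clock genes moved both ways. Of 16 measured, 4 rose, 3 fell and 9 did not pass (camera adjusted p = 0.842, leaning downward, while fry leaned upward). Arntl, the gene of the clock activator Bmal1, rose by 1.22 ± 0.12 and Nfil3, a repressor of D-box genes, by 1.51 ± 0.16. Dbp, an activator of the same genes, fell by 1.79 ± 0.25. Per2, a clock repressor gene, had -1.39 ± 0.23 on the brighter probe and 0.09 on its other probe. Of 18 immediate early genes 7 rose, 1 fell and 10 did not pass. Junb, Btg2 and Jund rose by 1.54 ± 0.27, 1.06 ± 0.20 and 0.52 ± 0.10, and Jun fell by 0.55 ± 0.11. Their camera adjusted p was 0.0274, and it was 0.489 with an estimated correlation. The call also ended with array weights (adjusted p = 0.0517), without the filter on dim probes (0.0898) and without control 1 (0.0721), and that of Jund ended under median scaling. Blocking by slide row left 0 of the 8 immediate early calls and a median of 0.43, the same as without the block to 2 decimals. Among stress lists, 2 of 24 genes of the unfolded protein and integrated stress response rose and 4 fell (camera adjusted p = 0.225). Chac1 was at 1.08 ± 0.22, Ppp1r15a at 0.55 ± 0.11, Ddit3 at -1.06 ± 0.15 and Derl3 at -1.64 ± 0.32. The median of that list was -0.30 with slide row as a block, against -0.085 without it. Of 18 NRF2 and oxidative stress genes 2 fell (camera adjusted p = 0.842, leaning downward, with a median of 0.05 and a mean of -0.0077), Nfe2l2 itself at -0.64 ± 0.11 and Ephx1 at -0.45 ± 0.11. Of 15 heat shock genes 1 rose, Hspb1 at 1.87 ± 0.19. The camera adjusted p of the heat shock list was 0.0525, with 0.0349 under median scaling and 0.113 under quantile normalization. Counts up and down adjusted over the list alone were 5 and 6 for clock, 9 and 1 for immediate early, 2 and 4 for stress response, 0 and 2 for NRF2 and 1 and 0 for heat shock genes.

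The remaining lists held few changed genes. Of 20 angiogenesis and hypoxia genes 1 rose and 2 fell (camera adjusted p = 0.121), with Ndrg1 at -1.21 ± 0.08, Egln3 at -0.56 ± 0.10 and Slc2a1 at 0.74 ± 0.17, whose call, like that of Lep, ended under median scaling. Of 19 sinusoidal endothelial markers 2 fell (camera adjusted p = 0.119), Rspo3 at -0.52 ± 0.09 and Stab1 at -0.53 ± 0.13. The median of the endothelial list was -0.37 with slide row as a block, against -0.20 without it. Of 11 cholangiocyte markers 2 fell (camera adjusted p = 0.138), among them Cd24a at -0.84 ± 0.09. Of 6 pancreatic acinar markers 1 fell, Cela1 at -1.24 ± 0.12 (camera adjusted p = 0.249). Of 8 adipose and mesothelial markers Car3, which hepatocytes also express, fell by 1.06 ± 0.11 and Lep rose by 0.48 ± 0.11 (camera adjusted p = 0.561, leaning downward, with a median of -0.04 and a mean of 0.0051). The other, dimmer Car3 probes gave -3.51 and -3.85. Of 9 muscle markers 0 passed limma and 1, Myh4, had an unadjusted p under 0.05 (fry adjusted p = 0.670), with Myh4 at 0.33 ± 0.13, Mylpf at 0.29 ± 0.14, Actg2 at -0.25 ± 0.15 and Tnnt3 at -0.09 ± 0.12 (camera adjusted p = 0.712). Of 29 oxidative phosphorylation genes 0 passed limma and 0 had an unadjusted p under 0.05 (fry adjusted p = 0.775), with Sdhc at 0.19 ± 0.09, Ndufa5 at -0.13 ± 0.11 and Ndufb8 at -0.09 ± 0.10 (camera adjusted p = 0.842). Their median of 0.02 turned to -0.10 under quantile normalization (camera adjusted p = 0.0449). Of 30 ribosomal protein genes 0 passed limma and 1 had an unadjusted p under 0.05, yet 29 had negative values with a median of -0.09, and camera gave an adjusted p of 0.0182, and of 0.764 with an estimated correlation. The ribosomal call also ended without control 2 (adjusted p = 0.186), without sEV 3 (0.0569) and within row 1 (0.0666). Rps19 and Rpl3 had -0.23 ± 0.08 and -0.22 ± 0.09, Rpl18 had -6.9e-05 ± 0.08, and Rps15 had 0.07 ± 0.09, which was negative under quantile normalization and median scaling. The control genes did not pass on their brightest probes, with Actb at -0.07 ± 0.11 (adjusted p = 0.691), and Alb at 0.15 ± 0.14 (0.496) and Gapdh at 0.16 ± 0.19 (0.598), both of which were negative under quantile normalization. Of the 6 other Gapdh probes 4 passed, at 0.45 to 0.49, and the others gave 0.14 and 0.46. Other probes of Mylpf (0.34, adjusted p = 0.0464) and Rps19 (-0.41, 0.0300) passed as well. Counts up and down adjusted over the list alone were 1 and 2 for angiogenesis, 0 and 2 for endothelial, 0 and 2 for cholangiocyte, 0 and 1 for acinar, 1 and 1 for adipose, and 0 and 0 for muscle, oxidative phosphorylation and ribosomal genes.

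In all, 19 of the 44 lists passed camera with the preset correlation, 11 upward and 8 downward. With a correlation estimated per list 0 passed, the lowest adjusted p was 0.489, and 1 list had an unadjusted p under 0.05. Immediate early genes had an estimated correlation of 0.0138, near the preset 0.01, yet their camera adjusted p went from 0.0274 to 0.489. The adjustment gave 0.489 to many lists alike, so that value does not rank them. Before adjustment the camera p of immediate early genes was 0.0118 with the preset. The lowest unadjusted p of any list with an estimated correlation was 0.0311. The option thus weakens the test even where the correlation hardly differs. Loss of a call under it cannot be put down to correlation between genes alone. The rotation test fry, which asks whether a list's genes move one way on balance and does not set them against other genes, passed 19 lists, of which 13 also passed camera. By fry, the adjusted p was 0.0660 for cholesterol, complement and stellate genes, 0.0583 for erythroid, 0.0701 for TGF-beta and 0.260 for ribosomal genes, which had passed camera. Lists that passed fry and not camera were apoptosis (fry adjusted p = 0.00307, downward), angiogenesis (0.0153, downward), T and NK cell (0.0153, upward), cytokines (0.0237, upward), niche factors (0.0317, upward) and cholangiocyte genes (0.0483, downward). The list median also turned sign with slide row as a block for cytokines (0.05), clock (0.23), B and plasma cell (-0.23) and muscle genes (-0.15). Probe positions on mouse build mm9, as the files give them, were chromosome 7 from 53967559 to 53967618 for Saa3, chromosome 5 from 88005187 to 88005246 for Sult1e1, chromosome 5 from 96389861 to 96389920 for Cxcl13, chromosome 8 from 23279041 to 23279100 for Ckap2, chromosome 4 from 118105534 to 118105593 for Cdc20 and chromosome 15 from 60751270 to 60751329 for A1bg.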

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

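The slide row fits were chosen after the data were seen, and the other alternatives before the data were examined; slide and scan date as blocks were not run, since all arrays share 1 of each. Without the filter on dim probes 810 genes passed (326 higher, 484 lower), 1502 passed the 2-fold criterion and the median of all genes was 0.20, with 37069 genes tested. Camera then passed 26 lists, against 19 with the filter, so some lists given above as not passing were called. Normexp left 488 genes in the 2-fold count and shrank dim genes, with Slc10a6 at 1.26 and Casc5 at -1.54. Median scaling left 999 higher genes. With the replicate block, 2210 genes passed, 1091 higher, and 1 of the 3 numbers had its best partner in its own pair. The counts with slide row as a block were 715 (251 higher, 464 lower) and within row 1 they were 594 (174 and 420), since 1 sEV array then carries the contrast; it is assumed to vary like the others. Of the 151 named genes past the threshold, 80 lost it with that block and 64 without the filter. Camera with an estimated correlation passed 0 lists. Leaving out 1 array gave 1348 to 2767 changed genes (623 to 1461 higher, 725 to 1306 lower), 889 to 1110 in the 2-fold count and 17 to 21 lists: 1348 without control 1, 1432 without control 2, 1683 without control 3, 1602 without sEV 2 and 1510 without sEV 3. Without sEV 1, the only sEV array in row 1, 2767 genes passed. The number of changed genes was below 3312 with any array left out, but the 2-fold count rose above 995 in some cases. The cause of these and the other changes was not tested.

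Genes that turned sign were near 0 or differed between probes. These were Tnnt3 (0.015 under normexp, from -0.15 without sEV 3 to 0.019 without sEV 1), Rps15 (-0.019 under quantile normalization, -0.0088 under median scaling, -0.019 in the authors' table), Alb (-0.16 under quantile normalization, -0.13 in the authors' table, -0.13 with slide row as a block and within row 1), Gapdh (-0.12, -0.12, -0.29 and -0.29), Actb (0.0015 with array weights, 0.018 without sEV 1) and Rpl18 (from -0.031 without control 1 to 0.029 without control 2, 0.0011 without control 3, 0.010 without sEV 3, 0.0034 with slide row as a block and within row 1). Of the 92 other probes followed, 17 kept the direction without passing, 6 newly passed and 5 turned sign. The other probes gave Bmf 0.10, Per2 0.092, Ndufb8 0.18, Asl -0.060 and Ly6c1 1.58, and the mean of probes gave Ndufb8 0.048 and Ly6c1 0.53. Signal over background limits dim genes, where only bounds can be given.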

Other observations

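All tests in this part were chosen after the results were seen, and the genes of this first paragraph were chosen after their values were seen. The cytochrome P450 genes Cyp2c67, Cyp2c68, Cyp2c69 and Cyp2c40 fell, with log2 fold changes of -1.81 ± 0.13 (SE, n = 3 per group) for Cyp2c67, -1.91 ± 0.13 for Cyp2c68, -1.78 ± 0.12 for Cyp2c69 and -1.39 ± 0.12 for Cyp2c40. Other members of the family went both ways, as Cyp2c44 fell by 0.97 while Cyp2c39 and Cyp2c70 rose by 0.50 and 0.62. These genes are similar in sequence, and signal shared between their probes was not tested. Hao2, a hydroxyacid oxidase gene, fell by 3.73 ± 0.23, Gdf15, a stress-induced hormone gene, by 1.97 ± 0.23, and Lpl, the lipoprotein lipase gene, by 1.70 ± 0.19. Nnmt, which encodes nicotinamide N-methyltransferase, rose by 2.42 ± 0.42. The kinase genes Pim1 and Pim3, which cytokine signals induce, rose by 1.46 ± 0.26 and 1.12 ± 0.24, and Bcl3, a nuclear partner of NF-kappaB, by 1.14 ± 0.29.

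The fall of 27 of 30 cell cycle genes could come from the arrays' positions, from fewer blood precursors or from less mature control livers. Position is argued against as the whole cause, since 22 of the 27 genes stayed past the threshold with slide row as a block, although 1 sEV array carries that contrast. Genes of erythroid precursors had a median log2 fold change of -0.60 with an SD of 1.36 between the fitted values of 13 measured genes, of which 6 fell and 2 rose (Hemgn and Icam4), so a part for lost precursors stays open, with 3 of the 13 also on the erythroid list. Fetal and juvenile liver genes had a median of -0.63, with 3 of 11 lower (Igf2bp3, Cdkn1c and Grb10), which leaves an age or maturity difference open; Hemgn, the precursor gene whose probe had the highest signal, had a normalized log2 signal of 7.68 in control and 8.73 in sEV livers. The vesicle treatment itself is a candidate explanation that these tests cannot separate from those left open.

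The rise of granulocyte genes may reflect more mature neutrophils or more blood left in the organ. Haemoglobin genes and Alas2 had a median of -0.70, at -0.45 in sEV 1, -1.78 in sEV 2 and -0.06 in sEV 3, and 0 of 6 passed. They thus showed no rise. These genes are also erythroid markers, and erythroid markers were lower. They therefore cannot gauge blood content on their own, and more blood stays open. Mature neutrophil genes had a median of 0.67, at 0.09, 0.93 and 1.13 in the sEV arrays, with 2 of 12 higher (Fpr2 and Il1r2). All 10 genes of a list for granulocyte precursors rose, with a median of 1.65 when 3 of them are taken at their bound. The list holds granule protein genes, the transcription factor genes Gfi1 and Cebpe, and Nkg7, which is also on the T and NK cell list. But that precursor list was written when most of its values were known, so more mature neutrophils stay open. On the mature list, the probe with the highest signal was that of Csf3r, which did not pass, with a normalized log2 signal of 6.71 in control and 5.81 in sEV livers.

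The shift of clock genes could come from another hour of harvest or from fasting. Genes of the Bmal1 phase lay above those of the Dbp and Per phase by a difference of medians of 1.73, but these lists hold the genes whose shift prompted them, so the value decides nothing. Nr1d1 rose by 0.66 although it belongs to the second phase, and the hour of harvest is not in the labels, so this explanation stays open and cannot be told apart from the treatment. PPAR-alpha targets, which fasting raises, had a median of -0.15, with 8 falling, 1 rising and 21 not passing. The genes of gluconeogenesis, in contrast, went the way fasting predicts. These lists point different ways and the feeding state is not in the labels, so fasting stays open.

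The 6 arrays can be split in 10 ways, too few for a share under 0.05. In 1 of the 10 splits, the real one, as many genes changed (3312, against at most 4 in the others), as many genes met the 2-fold criterion (995, against at most 55) and as many lists passed camera (19, against at most 17). Camera with the preset correlation passed at least 10 lists in each of the other splits, whereas fry passed 19 lists in the real split and 0 in the others. Each of the other splits mixes control and sEV arrays on both sides. A difference between the real groups then adds to the spread within each side and stays partly in the contrast. The counts of those splits are therefore not a null rate for either test.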
